A study of Homo sapiens with 6 samples.

How the data were processed

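RNA was extracted with TRIzol from NCI-H460 cells infected with lentiviral vectors that carried KRAB-dSpCas9 and a guide, and libraries were made from mRNA captured on beads, per the labels' protocols. Per the submitters' processing notes the tools were STAR and StringTie and the genome build was hg38; their versions, the annotation, filters and strand setting are not given in the sources used here. The authors deposited 1 table of FPKM values per gene and library, with 6 columns that matched the 6 samples by name, and FPKM are normalized for transcript length and for the mapped fragments of each library. The table held 52807 rows with 51447 distinct names, as symbols or, for 19021 names, as Ensembl gene identifiers. Of these, 47639 names matched a GENCODE 29 gene (build hg38), which gave the positions, gene types, transcript lengths and GC content used here, and every name matched the gene name table. The table used here listed 13087 of the 19951 protein-coding genes of GENCODE 29 (65.6%), so each count and gene list covers a part of the genes; the CPT1 isoforms were not analysed here. A total of 32 rows repeated another row with identical values above 0, 9 of them at 1 FPKM or more, and were kept once. The 37 mitochondrial genes were listed at 0 in all libraries, so a listed 0 may be a failed estimate and was not read as absence.

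Groups, comparisons, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. Values were log2(FPKM + 1), and the 8887 genes with a mean of at least 1 FPKM over the 6 libraries were tested. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. A model with 1 mean per group was fitted to all 6 libraries with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend), with no block and no further scaling. The 4 comparisons were sg1 against sgNTG, sg2 against sgNTG, the mean of both guides against sgNTG, and sg2 against sg1. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within a comparison, and the threshold was 0.05. Of 40 gene lists, the 30 with at least 5 tested members were tested with camera (preset correlation 0.01) and adjusted over the lists of a comparison. The replication-dependent histones, the cytosolic ribosomal proteins and the immediate early and heat shock genes were fixed as quality lists, the other tested lists as processes. No list call held with an estimated correlation in any comparison (lowest adjusted p = 0.155 over all lists and comparisons). With that setting camera rests on the residual degrees of freedom, which are few with 6 libraries. A lost call is therefore not by itself evidence of correlated members. The respiratory chain list with sg2 had an estimated correlation of -0.0195, below the preset 0.01. Its camera adjusted p still rose from 2.30e-05 to 0.260. The directional fry test, which asks whether the genes of a list move on balance one way and does not compare them with other genes, called 0 lists with sg1, 2 with sg2, 0 with both guides and 5 between the guides. With sg2 these were the respiratory chain and NF-kB lists. Between the guides they were the ribosomal protein, respiratory chain, histone, NF-kB and apoptosis lists.

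Named genes were, for both guides, the 10 largest rises and 10 largest falls among called genes whose libraries did not overlap, and for the other comparisons the 5 largest in each direction. Where fewer than 5 genes passed in a direction, the 5 of lowest p were given as values. Of each called list, up to 4 members of lowest p among those past the threshold over the list alone were named, otherwise the 2 of largest absolute change; measured genes beside the CPT1 loci were named too. Genes with an exact 0 in any library, clone, LOC and small RNA names, identifiers without a symbol, Y-linked genes and XIST were left out of the ranking. No called gene had an exact 0, and 12 of the 115 genes that differed between the guides were left out by name.

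Depth per library is unknown in FPKM. In genes of 107 nt the values of a library were close to whole multiples of 1 step, so the steps gave relative depths. The step was chosen to leave the fewest of these values off a whole number. Of the 33 to 46 values used per library, 88.9% to 94.1% then lay near a whole number, by a bound narrower than 0.1. Over a wider set of short genes, not cleared of those of 107 nt, 75.8% to 78.5% lay within 0.1. Counts of reads were not recovered, and no count test was run.

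The fit was tested on simulated data with 200 genes changed by known amounts in 20 runs, on the 8759 genes left by the filter in the first run. For both guides against sgNTG it recovered 10.4% of genes changed by 0.25 on the log2 scale, 51.8% at 0.5, 85.4% at 1 and 85.7% at 2, and 5.09% of its calls were false. For sg1 against sgNTG the recovered shares were 5.8%, 40.0%, 82.4% and 85.3%, and for sg2 against sgNTG 5.6%, 41.7%, 82.0% and 85.1%. For sg2 against sg1, simulated without a difference, a mean of 0.05 genes was called. A respiratory chain list lowered by 0.1 in both CPT1 groups was found by camera in 20 of 20 runs, with 0 other lists called; simulated genes varied independently.

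Alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, filters of 0.1 and 5 FPKM and no filter beyond a value above 0 in any library, median-of-ratios scaling, TPM rescaling over the listed genes, quantile normalization, limma without a trend and with robust variance, a replicate block, each library left out in turn, only the 4 libraries compared, a log2 fold change of at least 1, and for lists an estimated correlation, ranks and fry. The other 4 were chosen after seeing the data: removal of each library's loess trend on GC content and log2 transcript length (8718 genes with both), protein-coding genes only, no pseudogenes, and for the correlation between the guides a split of the controls, with 1 sgNTG library for each guide. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Values of some members of the gene lists are not reported here.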

Results

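Transcript levels were measured in NCI-H460, an established human large cell lung cancer line, after CRISPR interference against CPT1. CPT1 names the carnitine palmitoyltransferases that pass long-chain fatty acids into mitochondria for oxidation. In CRISPR interference a catalytically dead Cas9 fused to the KRAB repressor domain is guided to a gene and lowers its transcription without editing the DNA. The cells carried a nontargeting guide (sgNTG) or one of 2 guides against CPT1 (sg1 and sg2), with 2 libraries per group and 6 libraries in all. Infected cells were kept in 2 μg/ml puromycin from 48 h after infection. Values were FPKM, the fragments assigned to a gene, normalized for transcript length and for the mapped fragments of the library. Within groups the log2 values of the 8887 tested genes correlated across genes at Pearson r of 0.9908 to 0.9923, and between groups at 0.9884 to 0.9912. The listed values summed to between 251704 and 260500 FPKM per library. The absolute depth is unknown. The step between neighbouring low values gave depths, relative to the deepest library, of 0.853 and 1.0 for sgNTG, 0.937 and 0.972 for sg1, and 0.932 and 0.906 for sg2. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. The CPT1 isoforms themselves were not analysed here, so the lowering of the target by either guide is not shown by these values. Groups are named by their labels.

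Against the nontargeting guide, the mean of both CPT1 guides changed 1 gene past the threshold. RN7SL2, a copy of the 7SL RNA of the signal recognition particle (chromosome 14, 49862550 to 49862849), rose 2.66-fold (log2 fold change 1.41, SE 0.0841, limma adjusted p = 0.0149). It measured 2.74 and 2.96 FPKM with sgNTG, 10.6 and 10.2 with sg1, and 7.42 and 9.03 with sg2. No gene fell past the threshold, and 560 genes lay under an unadjusted p of 0.05. The 7SL copies are nearly identical in sequence, so reads can be split between them. The transcript is made by RNA polymerase III without a poly(A) tail. RN7SL1, a neighbouring 7SL copy, measured 3.04 and 3.71 FPKM with sgNTG and 8.07 to 11.7 over the 4 CPT1 libraries, without passing the test (limma adjusted p = 0.174). The RN7SL2 call was not made in limma's fit without a variance trend, with a replicate block or without a filter on low values. It was also not made without sgNTG replicate 1 or without sg1 replicate 2. The number of genes called became 7 without sgNTG replicate 2, 4 without sg1 replicate 1 and 2 without sg2 replicate 2.

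The genes with the next lowest p in this comparison are given as values, since none passed. HSPA6, a heat-inducible HSP70 chaperone, measured 16.8 and 17.4 FPKM with sgNTG and 22.9 to 24.2 over the CPT1 libraries (log2 fold change 0.44, SE 0.0435, limma adjusted p = 0.111). The transcriptional repressor BCL6 had a log2 fold change of 0.33 and the prostaglandin synthase PTGS2 of 0.21, each with a limma adjusted p of 0.310. On the negative side, the Polycomb subunit CBX2 measured 7.51 and 6.66 FPKM with sgNTG, 4.6 and 4.8 with sg1 and 4.1 and 3.92 with sg2 (log2 fold change -0.60, SE 0.0694, limma adjusted p = 0.174). The other 4 genes of lowest p on that side were the 7SL pseudogene RN7SL81P (-0.55), BOLA3, which acts in iron-sulfur cluster assembly (-0.30), the ATP synthase subunit ATP5MG (-0.37) and the pseudogene RPL36AP44 (-0.58), with limma adjusted p from 0.231 to 0.344.

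By gene list, the immediate early and heat shock list, fixed beforehand as a quality list, rose with the CPT1 guides on average, by a small amount. Its median log2 fold change was 0.10 (camera adjusted p = 3.64e-10). Of its 19 tested members, 9 rose adjusted over the list alone, none fell, and none passed over all genes tested. The estimated correlation of its members was 0.31, against the preset 0.01, and with it the camera adjusted p was 0.562. That setting also lowers the degrees of freedom, so the loss is not credited to the correlation alone. HSPA6 led the list, followed by HSPA1A (log2 fold change 0.20), the transcription factor FOS (0.21) and HSPA1B (0.18), each with a limma adjusted p of 0.0076 over the list alone or lower. HSPA1A and HSPA1B are nearly identical, so reads can be split between them. The cholesterol synthesis and uptake list rose with a median of 0.066 over 15 members (camera adjusted p = 0.0049; adjusted p = 0.562 with an estimated correlation). Its 2 members that rose adjusted over the list alone were HMGCS1, an early enzyme of the mevalonate pathway (0.29), and INSIG1, a regulator of sterol sensing (0.19). The NF-kB and inflammatory cytokine list had a median of 0.044 over 19 members (camera adjusted p = 0.0217; adjusted p = 0.562 with an estimated correlation). PTGS2 (0.21) and the cytokine IL6 (0.13) rose adjusted over the list alone. The mesenchymal and matrix list had a median of 0.064 over 14 members (camera adjusted p = 0.0221; adjusted p = 0.643 with an estimated correlation), with no member past the threshold over the list alone. COL4A1 had a log2 fold change of 0.14. The mitosis and G2/M list was lower, with a median of -0.038 over 19 members and none past the threshold over the list alone (camera adjusted p = 0.0217; adjusted p = 0.562 with an estimated correlation). CDC25C had a log2 fold change of -0.17 and BIRC5 of -0.15. The cholesterol list was not called without sgNTG replicate 1 (camera adjusted p = 0.116), and the NF-kB (0.303), mesenchymal (0.445) and mitosis (0.313) lists were not called without sgNTG replicate 2. The mitosis list was also lost without sg1 replicate 1 (0.136) and the mesenchymal list without sg2 replicate 1 (0.102). The mitosis (0.0713) and mesenchymal (0.138) lists were not called with a filter of 5 FPKM, and the mesenchymal list not with quantile normalization (0.0815). The NF-kB list was not called without a trend (0.135), without a filter (0.0936) or on ranks (0.164).

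**Figure D1:**
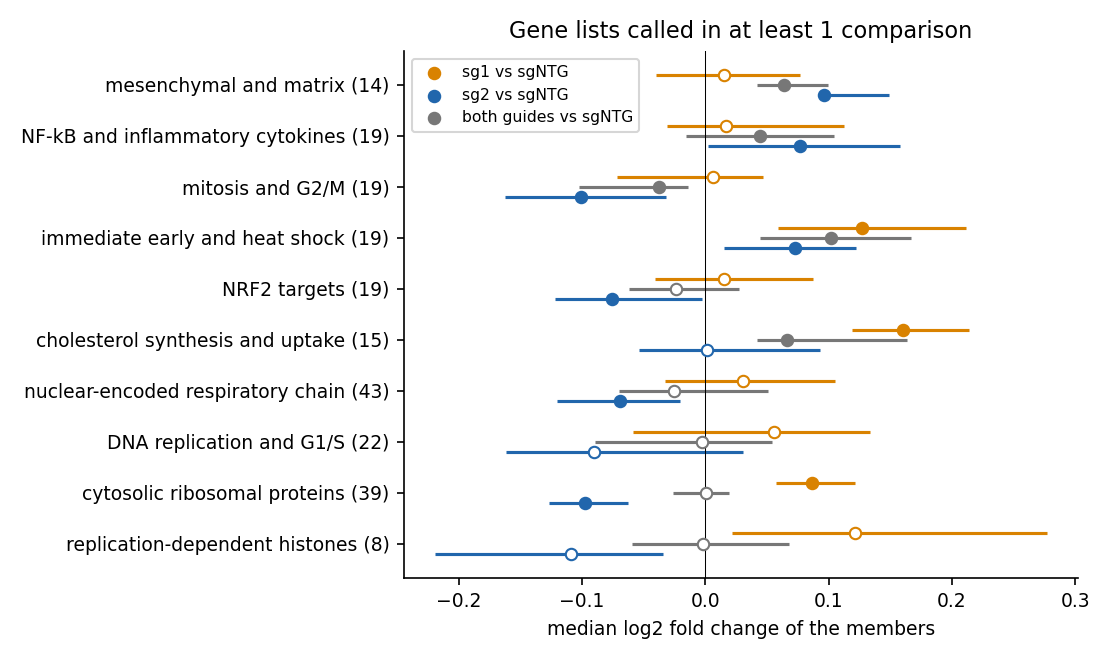
Median log2 fold change (x axis, log2 scale) of the tested members of each gene list called in at least 1 of the 4 comparisons (y axis, members in parentheses) for sg1, sg2 and both guides against sgNTG. Lines span the quartiles of the members, and filled points passed camera with its preset correlation; the cytosolic ribosomal proteins lay at 0.086 with sg1 and -0.098 with sg2.

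With sg1 alone, RN7SL2 was again the 1 gene that rose (2.97-fold, log2 fold change 1.57, SE 0.0971, limma adjusted p = 0.0190). No gene fell, and 882 genes lay under an unadjusted p of 0.05. The genes of next lowest p above 0 were HSPA6 (log2 fold change 0.46), the dynein light chain DYNLRB1 (0.43), the centromere protein CENPN (0.53) and the aldo-keto reductase AKR1B10 (0.24), with limma adjusted p from 0.126 to 0.132. Below 0 they were GRAMD1B, a sterol transfer protein (-0.25), the secreted glycoprotein STC1 (-0.25), RN7SL81P (-0.70), the protease inhibitor TFPI2 (-0.20) and the plasminogen activator PLAT (-0.38), each with a limma adjusted p of 0.126. The immediate early and heat shock list rose with a median of 0.13 (camera adjusted p = 1.53e-10; adjusted p = 0.630 with an estimated correlation). HSPA6, FOS (0.32), HSPA1A (0.26) and HSPA1B (0.25) led the 9 of 19 members that rose adjusted over the list alone. The cytosolic ribosomal protein list rose with a median of 0.086 (camera adjusted p = 1.53e-10; adjusted p = 0.595 with an estimated correlation). RPS15 (0.17), RPS21 (0.15), RPLP1 (0.17) and RPS6 (0.11) were among the 7 of 39 members that rose adjusted over the list alone. The cholesterol list rose with a median of 0.16 over 15 members (camera adjusted p = 3.96e-05; adjusted p = 0.595 with an estimated correlation). INSIG1 measured 19.1 and 20.9 FPKM with sgNTG and 26.03 and 25.78 with sg1, and rose adjusted over the list alone. The gene call was not made without a variance trend, without a filter on low values or with a replicate block. Nor was it made after removal of trends on GC content and transcript length. It was also not made without sgNTG replicate 1, sg1 replicate 1 or sg1 replicate 2. The number called was 6 without sgNTG replicate 2 and 3 without sg1 replicate 1.

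With sg2 alone, 1 gene rose and 1 fell, and 854 genes lay under an unadjusted p of 0.05. RN7SL2 rose 2.39-fold (log2 fold change 1.26, SE 0.0971, limma adjusted p = 0.0376). The gene that fell, ENSG00000285976, carries no symbol in the table and was named after its values were seen. It is a protein-coding gene on the plus strand of chromosome 6 (63572012 to 63583587) and fell by 2.49 on the log2 scale (SE 0.172, limma adjusted p = 0.0376), from 163 and 157 FPKM with sgNTG to 23.1 and 33.2 with sg2, with 124 and 98.5 in the sg1 libraries. It overlaps PTP4A1, a protein tyrosine phosphatase gene on the same strand (63521746 to 63583377). PTP4A1 measured 6.52 and 19.98 FPKM with sgNTG, 36.9 and 69.4 with sg1 and 153 and 140 with sg2, without passing the test (log2 fold change 3.55, SE 0.488, limma adjusted p = 0.134). The summed FPKM of the pair was 169 and 177 with sgNTG, 161 and 168 with sg1 and 176 and 173 with sg2. The genes of next lowest p above 0 were TFPI2 (log2 fold change 0.22), the hyaluronan-binding protein CEMIP (0.42), HSPA6 (0.43) and PTGS2 (0.30), each with a limma adjusted p of 0.105. Below 0 they were TXNIP, which binds thioredoxin (-0.39), BOLA3 (-0.46), CBX2 (-0.69), the ribosomal protein RPL23A (-0.24) and ATP5MG (-0.47), with limma adjusted p from 0.102 to 0.134. Neither gene was called without a variance trend, without a filter on low values, with a lower filter of 0.1 FPKM, with median-of-ratios scaling, quantile normalization or robust limma, or with only the 4 libraries compared. With a replicate block both calls were also lost. Neither was called without either sgNTG replicate or either sg1 replicate, while 5 genes were called without sg2 replicate 1, 1 without sg2 replicate 2 and 4 after removal of the GC and length trends.

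**Figure D2:**
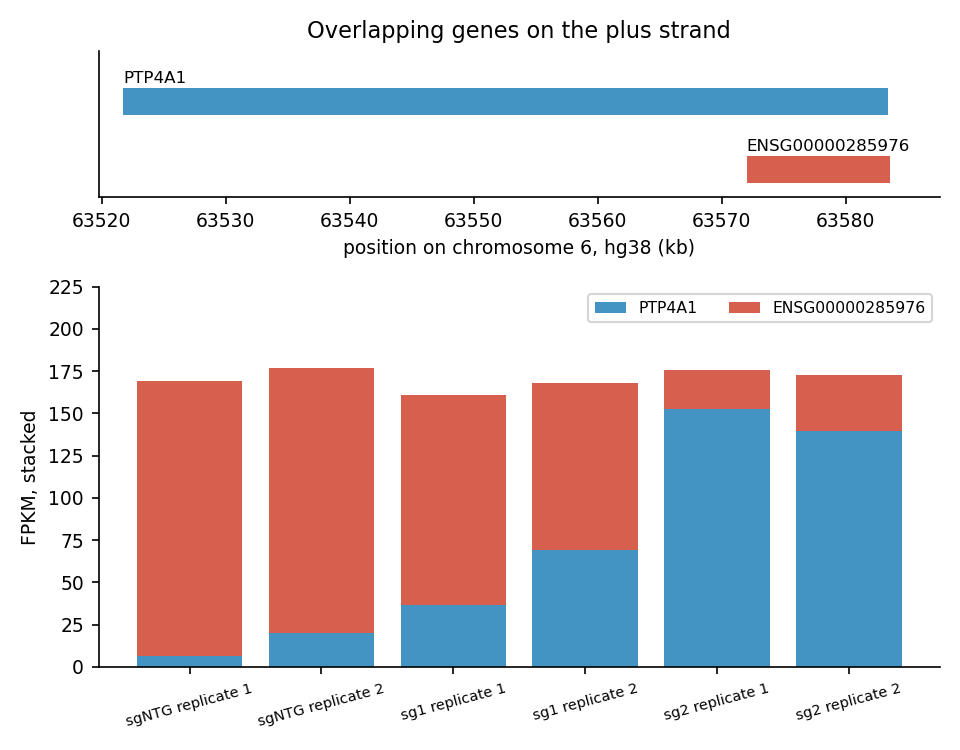
Annotated spans of PTP4A1 and ENSG00000285976 (upper panel, position in kb on chromosome 6, hg38) and their FPKM stacked per library (lower panel, y axis in FPKM, 1 bar per library). The summed height stays between 161 and 177 FPKM over the 6 libraries, while PTP4A1 goes from 6.52 in the lowest sgNTG library to 153 in the highest sg2 library.

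With sg2 the cytosolic ribosomal protein list fell, with a median of -0.098 over 39 members, 3 of which fell adjusted over the list alone (camera adjusted p = 4.53e-15; adjusted p = 0.260 with an estimated correlation). They were RPL23A (-0.24), RPS21 (-0.18) and RPL14 (-0.12). The nuclear-encoded respiratory chain list fell with a median of -0.069 over 43 members (camera adjusted p = 2.30e-05; adjusted p = 0.260 with an estimated correlation). ATP5MG (-0.47) and ATP5F1D (-0.42), subunits of ATP synthase, fell adjusted over the list alone. The NRF2 target list fell with a median of -0.075 over 19 members, 4 of which fell adjusted over the list alone (camera adjusted p = 1.11e-04; adjusted p = 0.329 with an estimated correlation). These were thioredoxin TXN (-0.16), AKR1B10 (-0.18), the epoxide hydrolase EPHX1 (-0.18) and the quinone reductase NQO1 (-0.11). The mitosis and G2/M list fell with a median of -0.10 and no member past the threshold over the list alone (camera adjusted p = 7.08e-04; adjusted p = 0.329 with an estimated correlation). BIRC5 had a log2 fold change of -0.23 and CDC20 of -0.18. The NF-kB and inflammatory cytokine list rose with a median of 0.077, and 5 of 19 members rose adjusted over the list alone (camera adjusted p = 7.08e-04; adjusted p = 0.264 with an estimated correlation). PTGS2 (0.30), IL6 (0.16), BIRC3 (0.36) and ICAM1 (0.36) had the lowest p. The mesenchymal and matrix list rose with a median of 0.096 over 14 members and none past the threshold over the list alone (camera adjusted p = 1.41e-04; adjusted p = 0.329 with an estimated correlation). The matrix protein THBS1 had a log2 fold change of 0.30. The immediate early and heat shock list rose with a median of 0.073 (camera adjusted p = 6.89e-04; adjusted p = 0.493 with an estimated correlation). HSPA6, DUSP6 (0.22) and HSPH1 (0.18) rose adjusted over the list alone. Without sg2 replicate 1 this last list was not called (camera adjusted p = 0.113).

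The labels give CPT1 as the target of both guides, so the changes with each guide were compared gene by gene. RN7SL2 was the 1 gene that rose with both guides, and no gene fell with both. Independent lists of these sizes would share 0.000113 genes. In 100 simulated sets of unchanged groups compared with the same control libraries 0 genes were shared, but these called a mean of 0.01 genes per guide, too few to measure what shared controls add. The log2 fold changes of the guides had a Pearson correlation of 0.41 across genes, which are not independent replicates. Unchanged groups compared with shared controls gave a mean correlation of 0.50, with a range of 0.42 to 0.58 over the draws. The covariance was 0.0126 against a simulated 0.0120, a difference of 0.00064. The changes had the same sign in 56.5% of genes, against 66.6% in the simulation. With the controls split, so that each guide was set against a different sgNTG library, the correlation was 0.0460 one way and -0.0185 the other, within the -0.110 to 0.110 of unchanged simulated groups. The same sign was then seen in 46.6% and 45.3% of genes, against 48.6% to 51.4% in the simulation. The split was chosen after seeing the data and leaves 1 control library per guide.

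**Figure D3:**
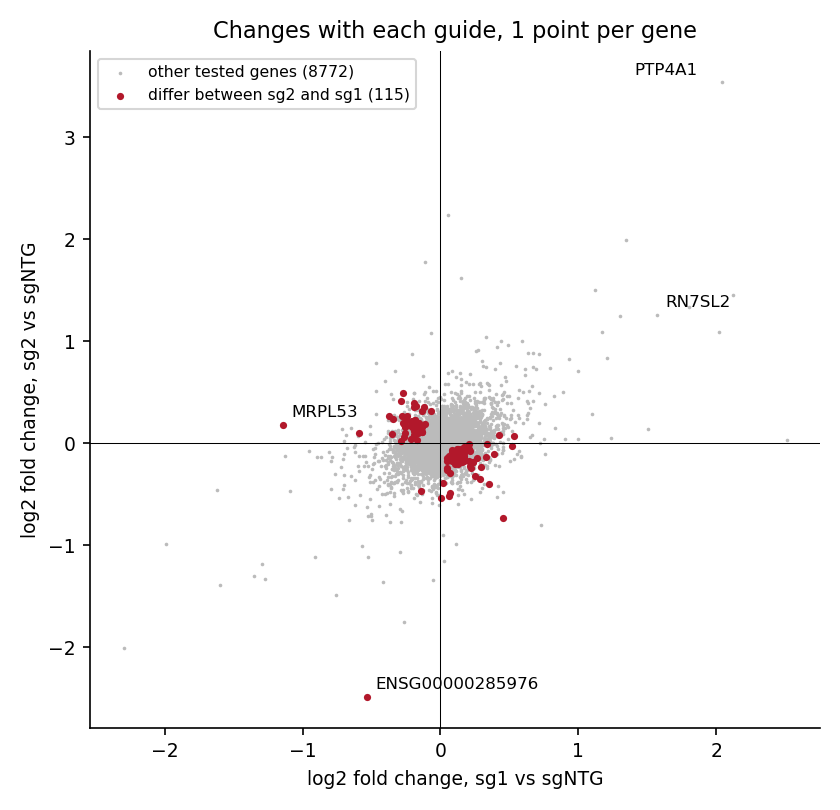
Log2 fold change with sg1 (x axis) and with sg2 (y axis) against sgNTG for the 8887 tested genes, 1 point per gene. The 115 genes that differed between the guides, in red, lie mostly in the upper left and lower right, and RN7SL2 lies in the upper right.

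The direct comparison of the guides gave the most calls. In all, 115 genes differed between sg2 and sg1, 46 higher and 69 lower with sg2, and 1514 genes lay under an unadjusted p of 0.05. In 111 of the 115 genes (96.5%) the sgNTG mean lay between the means of the guides, against 43.5% of all tested genes, and choosing genes for a large difference between the guides raises this share. The differences were small, with a median absolute log2 value of 0.33. Of the 46 genes higher with sg2, 43 were protein-coding. PAEP, the secreted glycoprotein glycodelin, measured 40.2 and 35.6 FPKM with sgNTG, 32.2 and 30.2 with sg1 and 54.1 and 52.97 with sg2 (log2 difference 0.76, SE 0.0669, limma adjusted p = 0.0133). CEMIP measured 33.5 and 32.1 FPKM with sgNTG, 26.9 and 26.4 with sg1 and 45.1 and 43.2 with sg2 (0.71, limma adjusted p = 0.0093). PLAT (0.64) and the insulin-like growth factor binding protein IGFBP1 (0.69) were also higher with sg2. The largest rise was that of MRPL53, a protein of the mitochondrial ribosome (1.32, SE 0.181, limma adjusted p = 0.0380). It measured 10.9 and 15.04 FPKM with sgNTG, 4.45 and 6.23 with sg1 and 15.7 and 13.7 with sg2. Of the 69 genes lower with sg2, 42 were protein-coding, 10 of them ribosomal protein genes, 23 were pseudogenes and 4 were of other types. Of the 8887 tested genes, 1064 were pseudogenes and 45 were ribosomal protein genes. The pseudogenes can share reads with their parent genes. The largest difference in either direction was that of ENSG00000285976 (-1.96, limma adjusted p = 0.0133), which overlaps PTP4A1. The named genes of the lower set were POC1B-GALNT4, a readthrough transcript that shares sequence with GALNT4 (-1.18), the chitinase-like protein CHI3L2 (-0.75), the neuropeptide NMB (-0.57), the stress-induced cytokine GDF15 (-0.54) and the noncoding RNA LINC01182 (-0.49). GDF15 measured 4.22 and 3.67 FPKM with sgNTG, 6.18 and 6.0 with sg1 and 3.68 and 4.06 with sg2 (limma adjusted p = 0.0496).

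**Figure D4:**
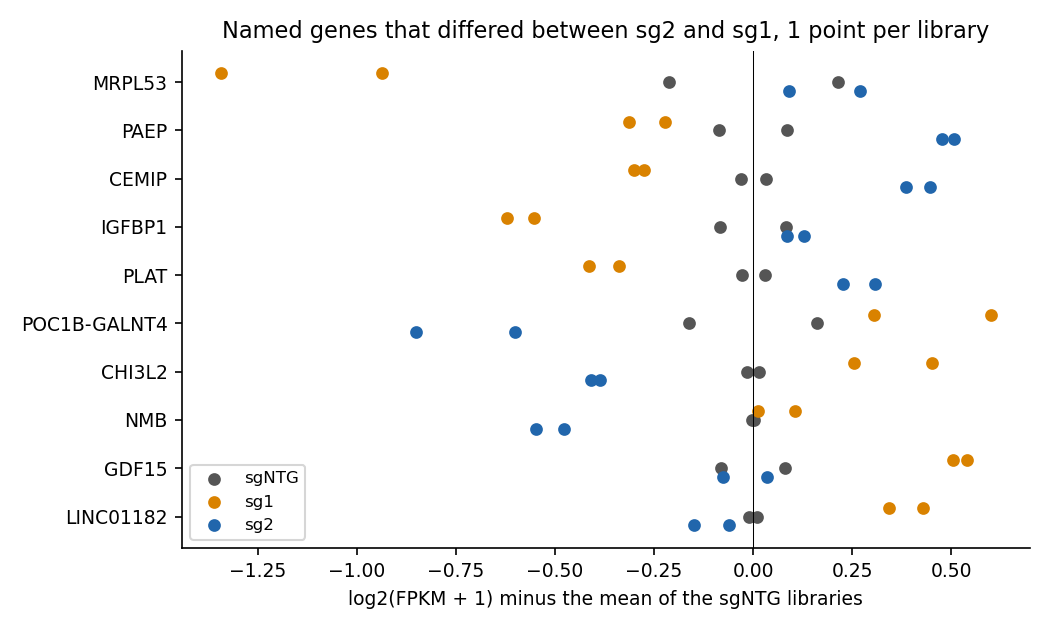
The 10 named genes that differed between sg2 and sg1, as log2(FPKM + 1) minus the mean of the sgNTG libraries (x axis, log2 units), 1 point per library and 2 libraries per group. The log2 differences go from 1.32 for MRPL53 to -1.18 for POC1B-GALNT4. The points of sg1 and sg2 do not overlap for any of these genes, which the rule for naming them required. Among all tested genes 48.6% did not overlap between sg1 and sg2.

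The number of genes that differed between the guides depended on the fit. It was 0 without a variance trend or without a filter on low values, 27 with a filter of 0.1 FPKM, 217 with a filter of 5 FPKM and 55 after removal of trends on GC content and transcript length. With a replicate block it was 5, with 5 higher and 0 lower with sg2. It was 26 without either sgNTG replicate, 5 and 4 without sg1 replicate 1 and 2, 12 and 6 without sg2 replicate 1 and 2, 26 with only the 4 libraries compared, and 3 at a log2 difference of at least 1. The split of 46 higher and 69 lower became 56 and 24 with TPM rescaling and 59 and 26 with quantile normalization.

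By gene list, the ribosomal proteins had the lowest camera p between the guides, with a median difference of -0.18 (camera adjusted p = 8.40e-22; adjusted p = 0.155 with an estimated correlation). Of 39 members, 30 were lower with sg2 than with sg1 adjusted over the list alone and 9 over all genes tested. RPS21 measured 163 and 160 FPKM with sgNTG, 183 and 176 with sg1 and 142 and 142 with sg2 (log2 difference -0.34, limma adjusted p = 0.0166). RPL23A (-0.29), RPLP1 (-0.31) and RPS6 (-0.18) were also lower. Ribosomal protein genes have many processed pseudogenes, so their reads can be split between copies. The respiratory chain list was lower with sg2 (median -0.14 over 43 members; camera adjusted p = 2.33e-06; adjusted p = 0.155 with an estimated correlation). NDUFB7 (-0.44), NDUFA6 (-0.29) and ATP5F1D (-0.36) were past the threshold over the list alone. The NRF2 targets were lower with sg2 (median -0.092; camera adjusted p = 9.11e-04; adjusted p = 0.351 with an estimated correlation), 5 of 19 adjusted over the list alone. AKR1B10 measured 459 and 468 FPKM with sgNTG, 541 and 552 with sg1 and 417 and 401 with sg2 (log2 difference -0.42, SE 0.0299, limma adjusted p = 0.0093). EPHX1 (-0.42) and the ferritin light chain FTL (-0.19) were also called over all genes. With quantile normalization the NRF2 list was not called and its median was 0.00075 (camera adjusted p = 0.391). The cholesterol list was lower with sg2 (median -0.13; camera adjusted p = 0.0022; adjusted p = 0.351 with an estimated correlation). INSIG1 (-0.33) and IDI1 (-0.30) were among 4 lower members over the list alone, and the sterol carrier STARD4 was higher (0.23).

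The replication-dependent histones were lower with sg2 than with sg1 (median -0.33 over 8 members; camera adjusted p = 0.0151; adjusted p = 0.351 with an estimated correlation). H2BC5 (-0.41), H1-2 (-0.39) and H2BC7 (-0.52) were lower over the list alone. DNA replication and G1/S genes were lower (median -0.14 over 22 members; camera adjusted p = 0.0390; adjusted p = 0.351 with an estimated correlation). The replication clamp PCNA was the 1 called member (-0.30, limma adjusted p = 0.0497). Mitosis and G2/M genes had a median of -0.080 with no member past the threshold (camera adjusted p = 0.0390; adjusted p = 0.375 with an estimated correlation). CDC20 had a difference of -0.27 and NEK2 of -0.18. The mesenchymal and matrix list was higher with sg2 (median 0.097; camera adjusted p = 0.0039; adjusted p = 0.375 with an estimated correlation). The integrin ITGA5 (0.22), the urokinase receptor PLAUR (0.13), THBS1 (0.42) and vimentin, VIM (0.11), were the 4 of 14 members higher over the list alone. The NF-kB list was higher (median 0.046; camera adjusted p = 0.0376; adjusted p = 0.351 with an estimated correlation). BIRC3, an inhibitor of apoptosis, was called over all genes (0.54, limma adjusted p = 0.0442), and PTGS2 (0.18), IL1A (0.22) and CXCL5 (0.20) were called over the list alone. The immediate early and heat shock list was lower with sg2 than with sg1 (median -0.080; camera adjusted p = 0.0089; adjusted p = 0.577 with an estimated correlation). JUNB (-0.19), FOS (-0.21) and HSPA1B (-0.15) were among 7 lower members over the list alone, and DUSP6 was higher (0.17). It was not called after removal of the GC and length trends (camera adjusted p = 0.0571), with quantile normalization (0.135) or without sg2 replicate 2 (0.150). The DNA replication list was not called without sg1 replicate 2 (0.252), without sg2 replicate 2 (0.150), after removal of the GC and length trends (0.0592) or with a filter of 5 FPKM (0.193). The histone list was not called without sg1 replicate 1 (0.0506), without a filter (0.254) or with a filter of 0.1 FPKM (0.123). The mitosis and NF-kB lists were called with sg1 replicate 1 left out and with no other library left out. Neither was called with a filter of 5 FPKM (0.193 and 0.0952). The mitosis list was also lost with TPM rescaling (0.0658), and the NF-kB list without a trend (0.0774) and on ranks (0.0752).

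The genes of fatty acid oxidation that surround CPT1 in its pathway showed no call with either guide. The 9 tested members of the carnitine shuttle and acyl-CoA synthetase list had a median log2 fold change of 0.012 with both guides (camera adjusted p = 0.905), and none passed adjusted over the list alone. CPT2, the inner-membrane partner of CPT1, measured 6.25 and 5.45 FPKM with sgNTG, 5.83 and 5.36 with sg1 and 5.28 and 5.35 with sg2 (log2 fold change -0.083, SE 0.0728, limma adjusted p = 0.881). TMLHE, an enzyme of carnitine synthesis, had the largest absolute change of the list (-0.091, SE 0.108). The 9 tested members of mitochondrial beta-oxidation had a median of -0.031 (camera adjusted p = 1.0), with ACOT9 at 0.13 (SE 0.0557) and the very long-chain acyl-CoA dehydrogenase ACADVL at 0.078 (SE 0.0624). Lists that camera likewise did not call in any of the 4 comparisons covered peroxisomal beta-oxidation, PPAR target genes, fatty acid synthesis and desaturation, triglycerides and lipid droplets, glycolysis and the TCA cycle. Of the fixed members, 9 of 16 were tested for the carnitine shuttle, 9 of 24 for mitochondrial beta-oxidation and 6 of 25 for PPAR targets. Members of a list without a call could still pass alone. The PPAR target PDK4 was higher with sg2 than with sg1 (log2 difference 0.27, limma adjusted p = 0.0380). With sg1, 1 PPAR target rose and 1 fell adjusted over the list alone. Stress and growth lists without a camera call were the amino acid and ATF4 stress response, the unfolded protein response, ferroptosis, p53 targets, hypoxia, apoptosis, ribosome biogenesis and MYC targets, autophagy and lysosomes, and glutathione and one-carbon metabolism. The interferon response, MHC class I and epithelial junction and keratin lists were not called by camera either. Directional fry called the apoptosis list higher with sg2 than with sg1 (adjusted p = 0.0451). Over these 20 lists the medians lay between -0.061 and 0.086 and the lowest camera adjusted p was 0.088. The 37 mitochondrial genes were listed at 0 in each library and were not tested.

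Genes beside the CPT1 loci did not pass the test in any comparison. With both guides the log2 fold change was -0.012 for LRP5, 0.090 for TESMIN and -0.17 for TPCN2, which lie beside CPT1A, and 0.082 for TYMP, -0.019 for ARSA and 0.059 for AP2A1, which lie beside CPT1B or CPT1C. Markers of other cell types were mostly low, with list medians of 0.0061 FPKM for endothelial, 0.0104 for alveolar and airway, 0.0886 for leukocyte, 0.149 for squamous and basal, 0.329 for neuroendocrine and 5.38 for fibroblast markers. The highest were NCAM1 at 103 FPKM, LUM at 47.2, SCG2 at 32.2, SERPINB5 at 24.3 and CD68 at 23.1, levels present in every library. Among them NCAM1 (log2 difference 0.38, limma adjusted p = 0.0280) and SCG2 (0.31, limma adjusted p = 0.0490) were higher with sg2 than with sg1. CHGA, the other tested neuroendocrine marker, had a log2 difference of -0.35 (SE 0.0698) and did not pass (limma adjusted p = 0.0796). Neither NCAM1 nor SCG2 was called without either sg1 replicate or either sg2 replicate. The lowest limma adjusted p with 1 of these libraries left out was 0.0959 for NCAM1 and 0.144 for SCG2. SCG2 was also not called without either sgNTG replicate.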

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

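The test of the genes kept after the GC and length correction, the correction itself and the tests of scaling by direction were chosen after the difference between the guides was seen. The labels give CPT1 as the target of both guides and name no isoform, and a direct test found that the guides differed. They differed in 115 genes, with log2 differences, sg2 minus sg1, of 1.32 for MRPL53, 0.76 for PAEP, 0.71 for CEMIP, 0.69 for IGFBP1 and 0.64 for PLAT. On the negative side they were -1.18 for POC1B-GALNT4, -0.75 for CHI3L2, -0.57 for NMB, -0.54 for GDF15 and -0.49 for LINC01182. They also differed in 10 gene lists by camera with its preset correlation, none of which was called with an estimated correlation. Among the quality lists the median differences were -0.18 for cytosolic ribosomal proteins, -0.080 for immediate early and heat shock genes and -0.33 for histones. Among the process lists the median differences were -0.14 for the respiratory chain, -0.092 for NRF2 targets and -0.13 for cholesterol synthesis and uptake. They were -0.14 for DNA replication, -0.080 for mitosis, 0.097 for mesenchymal and matrix genes and 0.046 for NF-kB and inflammatory cytokines.

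Whether scaling of the libraries is the cause for the genes higher with sg2 is not decided, though at least 40 of 46 passed under each of the 3 other scalings. TPM rescaling raised the median difference, sg2 minus sg1, of all tested genes from 0.0016 to 0.040, which favours these calls. Median-of-ratios scaling left that median at -9.7e-05, and quantile normalization gave 59 higher and 26 lower. None of them lowered sg2 against sg1 by much, so the counts show only that these calls held. Scaling may account for calls of the genes lower with sg2, of which 24 of 69 passed with TPM rescaling and 26 with quantile normalization, although each of these scalings called at least 80 genes in all. With median-of-ratios scaling, by contrast, 58 of the 69 passed, and the 11 lost had a median difference of -0.20 before and after. The 45 lower genes lost with TPM rescaling kept their direction, with a median difference of -0.23 (median SE 0.0327) before and -0.19 (median SE 0.0343) after, and the 43 lost with quantile normalization went from -0.23 to -0.15 (median SE 0.0327 and 0.0321). The share that was higher with sg2 went from 40.0% to 70.0% with TPM rescaling, a change that its upward shift of all genes favours by construction. GC content and transcript length may account for a part. The log2 differences between sg2 and sg1 correlated across genes with log2 length at a Pearson r of 0.149 and with GC content at -0.131, and the changes against sgNTG correlated with log2 length at -0.098 for sg1 and 0.065 for sg2. Rank (Spearman) correlations were larger, at 0.227 with length and -0.163 with GC content between the guides. Against sgNTG they were -0.157 for sg1 and 0.140 for sg2 with length. After correction 55 genes passed, fewer than 50% of the main count, the bound set before the correction was run. Whether they were the whole cause is not decided. The correction removed a smooth trend based on the longest transcript of each gene, and may leave part of such a bias. The simulation without a difference cannot decide the question either, since it held no trend on GC content or length. The 115 genes were also chosen in these same libraries. Of the 115 genes 52 still passed, more than the mean of 0.05 called in that simulation. The 63 that no longer did kept their direction, with a median absolute difference of 0.30 before and 0.25 after at an SE of 0.0445 on either side and a median limma adjusted p of 0.0615 after. The difference was smaller after the correction in 58 of the 63. The genes higher with sg2 had median changes against sgNTG of -0.20 with sg1 and 0.19 with sg2, and the lower ones 0.13 and -0.13. A change with 1 guide alone would leave the other near sgNTG, and unequal strength would move both guides the same way. Neither pattern was seen in the medians of the 115 genes as a set. Choosing genes for the difference favours opposite signs, so these medians do not decide against either as the cause. A difference between the guides in other targets, which was not tested, also stays open, as does any difference in handling that went with the groups.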

How the results depend on the processing

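The GC and length correction, the test of protein-coding genes alone, the test without pseudogenes and the split of the controls were chosen after the results were seen. Under both pseudocounts, TPM rescaling and the test without pseudogenes the counts of genes stayed within 1.5 times of 1 gene for sg1, 2 for sg2, 1 for both guides and 115 between the guides. Of the values of named genes, 1 reversed: TXN, sg2 against sg1, was 0.021 with quantile normalization. The correlation between the guides, 0.41, was 0.0460 and -0.0185 with the controls split, where by construction no library is shared. Among named genes the call was lost in 5 values for both guides, 7 for sg1, 23 for sg2 and 222 for sg2 against sg1, and kept or absent as before in 422, 370, 531 and 732; a call was gained in 2 values for sg2 and 17 between the guides. The median of 1 list turned, that of the NRF2 targets between the guides, which was 0.00075 with quantile normalization, where the list was not called. Calls of lists were lost without a turn in 22 values for both guides, 6 for sg1, 13 for sg2 and 41 between the guides. Absolute depth is unknown, and what it limits was not tested. Without a filter on low values 30317 genes were tested and the counts were 0, 0, 0 and 0 for sg1, sg2, both guides and sg2 against sg1, with 1904, 1991, 1590 and 2646 genes at an unadjusted p under 0.05. With a filter of 0.1 FPKM they were 0 for sg2 and 27 between the guides over 16572 genes, and with a filter of 5 FPKM 217 between the guides over 5020 genes, 108 of them among the 115. limma without a trend gave 0, 0, 0 and 0, with 769, 773, 546 and 1408 genes at an unadjusted p under 0.05, and the robust fit 0 for sg2, with 863. Median-of-ratios scaling gave 0 for sg2, with 881, and quantile normalization 0, with 844. Only the 4 libraries compared gave 0 for sg2 and 26 between the guides, where fewer samples set the spread, and a log2 fold change of at least 1 left 3 of the 115. The GC and length correction gave 0 for sg1, with 848 genes at an unadjusted p under 0.05, 4 for sg2 and 55 between the guides, and protein-coding genes alone gave 0 for sg1, 1 for sg2 and 0 for both guides, which leaves out RN7SL2 by construction. Genes changed in the same direction by both guides, 1 in the main test, were 0 without a filter, with the 0.1 FPKM filter, with median-of-ratios scaling, quantile normalization, no trend, the robust fit, the GC and length correction and protein-coding genes alone. With each library left out in turn, where the lone library of a group is assumed to vary like the others, the ranges were 1 to 6 genes for sg1, 0 to 5 for sg2, 0 to 7 for both guides, 4 to 26 between the guides and 0 to 3 in the same direction. Gene lists called, 3 for sg1, 7 for sg2, 5 for both guides and 10 between the guides, became 0, 0, 0 and 0 with an estimated correlation, 0, 2, 0 and 5 with directional fry, and 17, 15, 6 and 25 with mixed fry, which asks for change in either direction; the 5 FPKM filter gave 3 for both guides and 6 between the guides, and libraries left out gave 2 to 5 and 6 to 9. Except where the construction is named, the cause was not tested.

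The replicate numbers did not pair the libraries: deviations from the group means correlated at 0.034, -0.028 and 0.06 between same-numbered libraries. With the replicate block the counts were 0 for sg1, 0 for sg2, 0 for both guides, 5 between the guides and 0 in the same direction, with 871, 832, 555 and 1461 genes at an unadjusted p under 0.05, and the list counts were as in the main test. The CPT1 isoform change was not analysed here.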

Other observations

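The test of PTP4A1 and its overlapping gene, and the tests on the other 7SL copies, were chosen after the values were seen. STC1 measured 281 and 287 FPKM with sgNTG, 237 and 241 with sg1 and 332 and 334 with sg2 (log2 difference 0.48, SE 0.0277, limma adjusted p = 0.0064), and TFPI2 measured 1371 and 1396 with sgNTG, 1190 and 1221 with sg1 and 1620 and 1611 with sg2 (0.42, limma adjusted p = 0.0064). The collagen COL3A1 measured 9.4 FPKM in each sgNTG library, 12.6 and 13.01 with sg1 and 10.1 and 9.85 with sg2, and the difference between the guides did not pass (log2 difference -0.33, limma adjusted p = 0.0516). The snoRNA SNORA2A measured 0.477 and 0.405 FPKM with sgNTG, 1.76 and 1.74 with sg1 and 1.7 and 1.41 with sg2, without passing the test (limma adjusted p = 0.174 with both guides); it was chosen after its values were seen.

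RN7SL2 rose with both guides, and its copies RN7SL1 and RN7SL3 had log2 fold changes of 1.28 and 0.70 without passing. A carry-over as large as the rise of RN7SL2 is argued against for small nucleolar, small nuclear, small Cajal body and ribosomal RNAs and replication-dependent histones. The 77 tested genes of these classes had a median log2 change of 0.084, with quartiles of -0.042 and 0.24. Genes annotated as miscellaneous RNA, the type of RN7SL2 itself, were not in this set. A carry-over of other RNAs of that type without a poly(A) tail was not tested and stays open. A smaller general carry-over stays open, since 49 of the 77 were higher and 28 lower, and SNORA2A had a log2 fold change of 0.88. Reads moved from other 7SL copies are argued against as the whole cause: the summed FPKM of the 680 listed 7SL genes was higher by 0.47 on the log2 scale (SE 0.0698), above the bound of 0.2 for such a move and short of the 0.5 set beforehand against it. To supply the rise of RN7SL1, RN7SL2 and RN7SL3, 15.4 FPKM with sg1 and 12.1 with sg2, the other copies would have to change by -0.79 and -0.58, and they changed by -0.033 and 0.25 (SE 0.0753 each), while the copy RN7SL81P lost 2.07 and 1.33 FPKM, so a move of part of the reads stays open. A carry-over limited to 7SL RNA, which is very abundant in cells, and a change in 7SL RNA with the CPT1 guides both stay open, and a biological cause was not tested.

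PTP4A1 and ENSG00000285976 share strand and sequence span, and their FPKM moved in opposite directions with sg2. A candidate explanation is that StringTie divided the same reads differently between the overlapping genes. The summed FPKM of the pair changed by 0.0092 on the log2 scale with sg2 (SE 0.0381), as that explanation needs, against 3.55 for PTP4A1 and -2.49 for ENSG00000285976. A switch between transcripts of the pair would leave the same sum, stays open and was not tested.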
